A study of Mus musculus with 9 samples.

How the data were processed

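RNA of 3 cell populations sorted from mice with 1 copy of the fractalkine receptor gene Cx3cr1 replaced by a green fluorescent protein reporter was measured on Affymetrix mouse gene arrays, with 3 biological replicates per population and 9 arrays in all. The populations were T cell zone macrophages (TZM) of lymph nodes, CD8a+ dendritic cells (DC) and microglia. Per the labels' protocols, tissue was digested with DNase I and collagenase I, enriched on beads and sorted by flow cytometry. TZM were GFP-high, MertK+, CD11b+ and CD169 negative, brain macrophages were GFP-high, CD11b+ and CD45+, and DC were CD64 negative, CD11c-high, MHC class II-high and CD8a+. The labels disagree on the source of the DC: the sample fields give the lymph node, and the sorting protocol gives the spleen. Genes that encode the sort markers are no finding between the populations.

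The values are log2 expression levels deposited by the authors, made per the submitters' processing notes with Affymetrix Expression Console 1.3.1 and robust multi-array averaging (RMA), which corrects background, normalizes across arrays and summarises probes per probe set. The deposited table held 35556 probe sets for 9 samples, with values from 2.04 to 13.6. The table of platform annotation used here gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12146, and of the first 21698 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes. Probe sets without a single symbol were left out of the gene tests, except in the alternative that tested every probe set. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays was kept, which left 19938 genes. Array medians over these genes ran from 4.90 to 5.02. No detection call was used, so levels near the low end of the scale are not separated from background, and fold changes against such levels tend to understate a difference. The number of arrays limits the precision.

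Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 9 arrays in 1 fit). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors (SE) of log2 fold changes come from this fit, and all adjusted p-values of single genes are limma's. Overlaps of calls between comparisons that share arrays were set beside the overlap of independent lists of the same sizes and beside 50 simulations of unchanged groups, which under these calling criteria do not measure the effect of shared arrays. The shared arrays were not split, since with 3 arrays a part would keep only 1, so part of an excess may come from them. The distance between 2 arrays was the Euclidean distance over all genes, and the difference of distances was tested by an exact two-sided permutation of the 6 DC and microglia arrays (20 assignments). The 33 gene lists, among them markers of other cell types, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists and comparisons. Directional fry, the alternative, does not compare a list with other genes. A list's count of higher and lower members uses the calls over all genes, and the count adjusted over the list alone is given where it differs. List members without a single-symbol probe set were not analysed here. Several lists hold genes of the sort gates, and no list was tested without them. Examples are Cd8a and Itgax among type 1 DC genes, H2-Aa and H2-Eb1 among class II genes, and Mertk and Fcgr1 in the macrophage core.

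The comparisons, the lists, the named genes and all but 3 of the alternatives were fixed before the data were examined. Named genes were the 8 with the largest change in each direction per comparison among called genes whose arrays did not overlap, the 10 with the largest smaller change for genes apart from both other groups, up to 4 called members per list and comparison by size of change, and 33 fixed genes. Predicted genes, clones, small RNAs and antigen receptor segments were passed over. Tested on simulated data of 19938 genes with 200 changed genes, the fit recovered 91% of genes changed by 1.5 and 98% of genes changed by 2 (log2) between TZM and DC, and 94% and 98% between TZM and microglia, with 0 and 1 false calls. A shifted list was called in 2 of 2 comparisons, and 0 of 97 other list tests were called. The simulated genes varied independently, so this does not measure false list calls among correlated genes.

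Alternatives were no minimum fold change, a filter on level (at least 6 in at least 3 arrays), median centring, quantile normalization over the genes, the mean of a gene's probe sets, every probe set of the table, only the compared groups in the fit, trended and robust eBayes, array weights, the replicate number as a block, and each array left out. For lists, camera with an estimated correlation and fry were run. For distances, correlation and the 1000 most variable genes were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.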

Results

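The series sets resident macrophages of the lymph node T cell zone, a population its title ties to the removal of apoptotic cells, against CD8a+ DC and against microglia. CD8a+ DC are cross-presenting dendritic cells, and microglia are the resident macrophages of the brain parenchyma. Each population was measured in 3 arrays. Levels are log2 RMA values, given as mean ± SD.

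The TZM profile stood apart from both other populations. The mean distance between TZM and microglia arrays was 102.7 (range 100.6 to 106.6 over 9 pairs), and that between TZM and DC arrays was 108.5 (106.2 to 110.8). DC and microglia were 123.1 apart. Distances within a population averaged 43.1 in TZM, 31.6 in DC and 36.1 in microglia. TZM lay nearer to microglia by 5.86, with an exact permutation p of 0.1, the smallest that this design allows, so the difference cannot reach 0.05. Each of the 3 TZM arrays was nearer to microglia, by 7.25, 3.65 and 6.67.

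**Figure D1:**
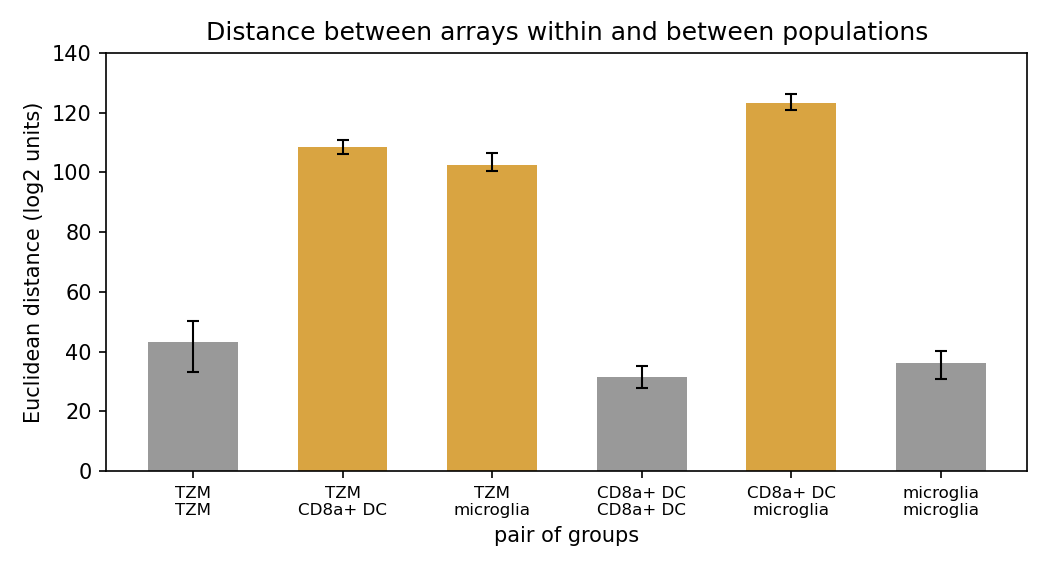
Mean Euclidean distance over 19938 genes (log2 units, y axis) between arrays within each population (grey) and between populations (ochre), with bars from the lowest to the highest pair. Distances between populations lie at 102.7 to 123.1, above the 31.6 to 43.1 within them.

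The first comparison asked how TZM differ from dendritic cells. Most genes of the macrophage core list were higher in TZM, and most genes of the DC list were lower. The complement genes C1qa and C1qc, whose products also bind apoptotic cells, were higher in TZM by 7.33 (SE 0.22, adjusted p = 1.2e-07) and 7.13 (SE 0.13, adjusted p = 8.6e-09). Csf1r, the receptor for the macrophage growth factor CSF1, was at 11.22 ± 0.09 (SD, n = 3) in TZM and 5.21 ± 0.33 in DC. In the other direction Xcr1, a chemokine receptor of type 1 DC, was at 4.40 ± 0.13 in TZM and 10.71 ± 0.05 in DC. Flt3, a growth factor receptor of DC, had a log2 fold change of -4.83 (SE 0.08, adjusted p = 8.6e-09). In all, 1743 of 19938 genes were called, 939 higher and 804 lower in TZM. This balance turned with every probe set tested (1123 higher, 1274 lower) and with no minimum fold change (1960 higher, 2065 lower).

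Of the 36 measured genes shared by tissue macrophages, 32 were higher in TZM and 0 lower (median 2.89, camera adjusted p = 2.0e-35), among them Selenop at 5.89, Ctsd at 5.35 and the phosphatidylserine-linked receptor kinase Mertk at 6.43, which was also a sort marker. Of 19 genes of other lymph node and splenic macrophages, 14 were higher (adjusted p = 7.5e-14), with Clec4n at 5.44, the phosphatidylserine receptor Timd4 at 5.02 and the iron exporter Slc40a1 at 4.52. The microglia list had 11 of 23 members higher and 0 lower (adjusted p = 2.6e-06). These included the purinergic receptors P2ry13 (5.61) and P2ry12 (4.98), Tmem119 (4.64) and Cx3cr1 (4.91). Cx3cr1 is also a gate gene, since 1 copy was replaced by the reporter that TZM were sorted on. Sall1, a transcription factor of microglia, was at 4.48 ± 0.12 in TZM and 4.47 ± 0.15 in DC. Of 28 DC genes, 26 were lower in TZM and 0 higher (adjusted p = 2.6e-31), such as Btla at -4.76 and Dpp4 at -4.53. Of 17 type 1 DC genes, Cd8a and Itgax of the DC gate among them, 15 were lower and 0 higher (adjusted p = 3.3e-22). Clec9a, a receptor for dead cells, was at -6.17. The transcription factors Zbtb46, Batf3 and Irf8 had log2 fold changes of -1.53, -1.29 and -0.93, of which the last did not pass the fold minimum.

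Of 36 genes for the uptake of dead cells (efferocytosis), 16 were higher in TZM, 3 lower and 17 not called (camera adjusted p = 3.9e-08, and adjusted p = 0.054 with an estimated correlation). Beside C1qa, C1qc, Mertk and Timd4, Axl was higher by 4.90. The bridging molecule Gas6 was higher by 1.11, and without DC replicate 3 by 0.96, under the fold minimum. Mfge8 had a log2 fold change of 0.43 (adjusted p = 0.083). Lysosomal genes were higher for 26 of 47 members and lower for 3 (adjusted p = 1.2e-18), with the acid phosphatases Acp2 and Acp5 at 4.17 and 4.14. In the list for lipid handling, 15 of 22 members were higher and 1 lower (adjusted p = 4.1e-14). The cholesterol exporter Abca1 was higher by 4.86, the oxysterol receptor Nr1h3 by 4.77, and Apoe was at 13.03 ± 0.17 against 9.53 ± 0.22, while the scavenger receptor Cd36 was lower, at -3.87. Complement and Fc receptor genes had 10 of 18 members higher and 1 lower (adjusted p = 1.4e-10).

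Of 18 genes for MHC class II and co-stimulation, 8 were lower in TZM, 1 higher and 9 not called (adjusted p = 4.1e-05). Ciita, the class II transactivator, was at 5.98 ± 0.03 in TZM and 9.21 ± 0.05 in DC. H2-Aa, used in the sort of the DC, was at 11.46 ± 0.11 and 12.44 ± 0.04 (log2 fold change -0.98, adjusted p = 0.12). This p-value rests on a spread pooled over all 9 arrays, microglia included, and not only on the SDs of TZM and DC. Cd74 had a log2 fold change of -1.01 (adjusted p = 0.037). Leaving out any TZM or DC array ended this call (log2 fold change -0.96 to -1.05, adjusted p = 0.065 to 0.11). So did the replicate block (-1.01, adjusted p = 0.052), quantile normalization (-0.87, adjusted p = 0.061) and every probe set tested (-1.01, adjusted p = 0.059). The Cd74 call held with only TZM and DC in the fit, with median centring and with array weights. It also held with trended and robust eBayes and when any single microglia array was left out. The list for MHC class I and cross-presentation, with 1 higher and 4 lower of 18, was not called (adjusted p = 0.061), but was without TZM replicate 1 (adjusted p = 0.031). Of 17 maturation genes, 7 were lower and 0 higher (adjusted p = 3.1e-06), including Il12b (-4.20) and the migration receptor Ccr7 (-1.96). Cell cycle genes were lower for 21 of 29 members and higher for 0 (adjusted p = 2.4e-20). Mki67, a marker of cycling cells, had a log2 fold change of -2.12, and Kif11 one of -2.22.

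Secreted mediators went both ways. Of 30 cytokine and chemokine genes, 12 were higher and 6 lower (camera adjusted p = 0.0069, and adjusted p = 0.35 with an estimated correlation). Ccl12, Ccl8, Il1a and Pf4 were higher by 7.51, 6.70, 6.53 and 5.13. Of 25 interferon-stimulated genes, 13 were higher and 1 lower (adjusted p = 1.2e-07, and adjusted p = 0.060 with an estimated correlation), with the RNA sensor Ddx58 at 4.21 and Mx1 at -1.60. The list of lineage regulators had 11 higher and 5 lower of 28 and was not called (adjusted p = 0.39), and its median of -0.09 differed in sign from its mean of 0.70. Immediate early genes, which respond to tissue digestion, had 2 higher and 6 lower of 23 (adjusted p = 0.46).

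The second comparison asked how TZM differ from the macrophages of the brain. Most of the macrophage core was not called between TZM and microglia. Most microglia genes were lower in TZM, and the lists for class II and interferon-stimulated genes were called higher. The phospholipase Pla2g2d was at 12.13 ± 0.09 (SD, n = 3) in TZM and 5.27 ± 0.09 in microglia. The nuclease Dnase1l3 was higher in TZM by 7.35 (SE 0.13, adjusted p = 1.3e-08), and it was as high in DC, at 11.78 ± 0.04. Spic, a transcription factor of iron-recycling macrophages, was higher by 6.43. In the other direction Fcrls was lower in TZM, at -6.89 (SE 0.08, adjusted p = 2.6e-09), and Sparc at -6.38. In all, 1526 genes were called, 848 higher and 678 lower in TZM, and with every probe set tested the balance turned (1081 higher, 1252 lower).

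**Figure D2:**
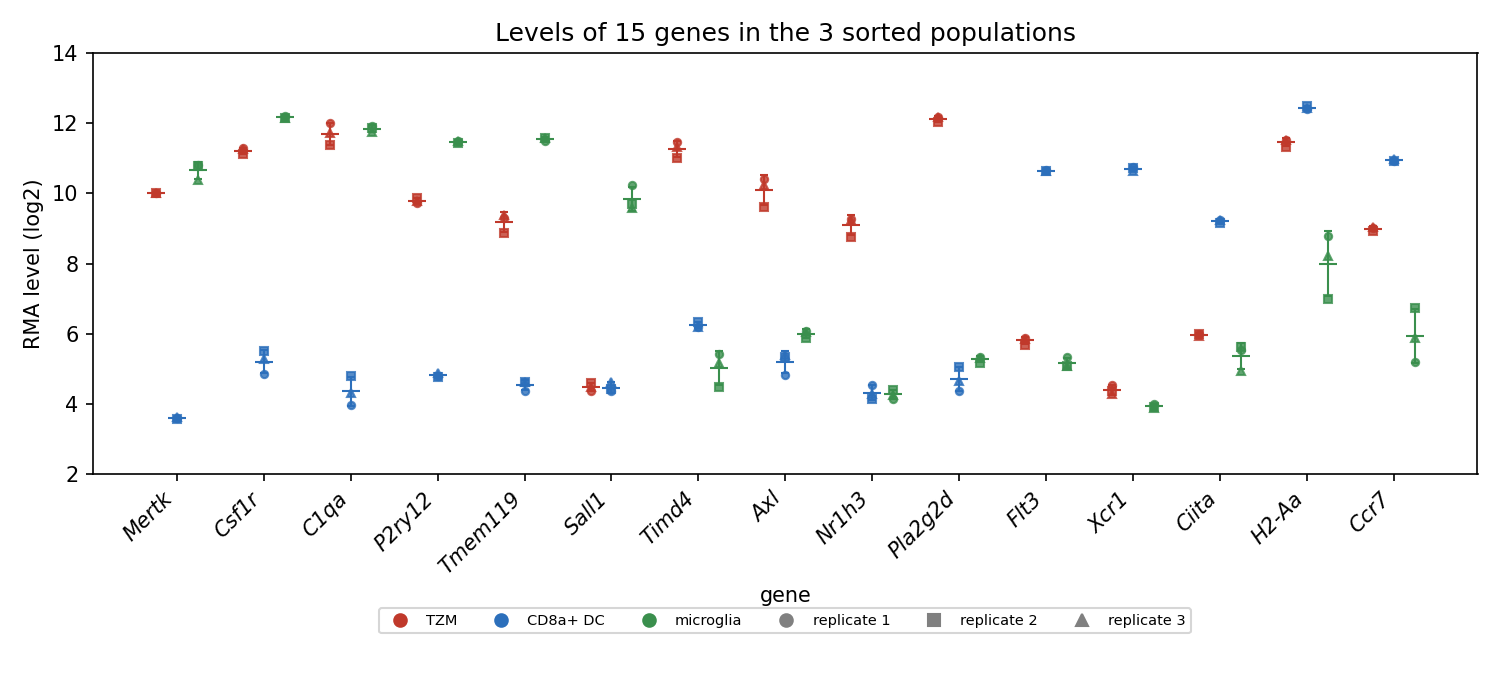
Log2 RMA levels (y axis) of 15 genes (x axis) in TZM (red), DC (blue) and microglia (green). Points are the 3 arrays of a population, with the shape giving the replicate, and bars show the mean ± SD. Sall1 is at 9.84 in microglia and near 4.5 in both other populations, and Pla2g2d is at 12.13 in TZM alone.

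Of 23 microglia genes, 20 were lower in TZM and 0 higher (median -3.74, adjusted p = 5.3e-32). Sall1 was lower at -5.35 and the fructose transporter Slc2a5 at -5.51. Tmem119 (-2.38) and P2ry12 (-1.68) were lower than in microglia although higher than in DC. In the macrophage core, 25 of 36 genes were not called, 10 were lower and 1 higher (adjusted p = 7.2e-06), and C1qa and C1qc had log2 fold changes of -0.15 and -0.03. Of 18 complement and Fc genes, 7 were lower, such as C3ar1 at -3.38, and 2 higher, among them Cfp, properdin, at 5.45 (camera adjusted p = 0.019, adjusted p = 0.086 with an estimated correlation, and adjusted p = 0.054 without TZM replicate 3). The list of lymph node and splenic macrophage genes had 10 higher and 3 lower of 19, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.23 with an estimated correlation). Vcam1, an adhesion molecule, was higher by 5.05.

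Efferocytosis genes were split, with 9 higher and 8 lower of 36 (adjusted p = 0.80, median -0.03, mean 0.22). Timd4 (6.24), Axl (4.09) and Colec12 (3.22) were higher in TZM, while Lrp1 (-2.92) and Gas6 (-1.57) were lower and Mertk stood at -0.63. Lipid handling genes were higher for 12 of 22 and lower for 2 (camera adjusted p = 2.6e-07, and adjusted p = 0.059 with an estimated correlation). Nr1h3 was higher by 4.82, the fatty acid binding protein Fabp5 by 4.43 and Apoe by 1.54. Lysosomal genes had 6 higher and 3 lower of 47 (camera adjusted p = 0.0047, adjusted p = 0.39 with an estimated correlation, and adjusted p = 0.0504 with the level filter), with Acp5 at 6.58 and the sulfatase Arsb at -3.91.

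Class II genes were higher in TZM for 9 of 18 members and lower for 3 (adjusted p = 9.1e-05). H2-Aa was higher by 3.46 and Cd74 by 2.94, while H2-Oa (-1.12) and H2-Ob (-1.05), which restrain peptide loading, were lower. The class I list had 6 higher and 0 lower of 18 (adjusted p = 7.2e-06), with Tap1 at 2.04. Of 25 interferon-stimulated genes, 16 were higher and 0 lower (adjusted p = 4.4e-15), such as Iigp1 at 3.48 and Irf7 at 2.94. DC genes were higher for 11 of 28 and lower for 1 (adjusted p = 2.2e-10), with Anpep at 4.97 and Ccr7 at 3.06. Maturation genes had 9 higher and 1 lower of 17 (adjusted p = 8.7e-09), with Ccl5 at 4.53, Ccl22 at 3.42 and Cd83 at -1.78. Type 1 DC genes had 5 higher and 1 lower of 17 (camera adjusted p = 0.00091, and adjusted p = 0.12 with an estimated correlation). Cytokine genes had 10 higher and 9 lower of 30 (adjusted p = 0.40), with Cxcl9 at 6.63 and Ccl4 at -3.64. Regulators had 5 higher and 6 lower of 28 (adjusted p = 0.89), and cell cycle genes 2 higher and 0 lower of 29 (camera adjusted p = 0.00026, and adjusted p = 0.21 with an estimated correlation).

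Immediate early genes were lower in TZM than in microglia for 16 of 23 members and higher for 0 (median -1.27, adjusted p = 4.1e-19). Nr4a1 had a log2 fold change of -3.11, Ier3 -3.36 and Btg2 -2.71. Nr4a1 is also a member of the regulator list, and Ccl4 of the cytokine list. Transcripts of Ttr, an abundant product of the choroid plexus, were at 12.15, 5.48 and 11.83 in the 3 microglia arrays and at 4.23 ± 0.20 in TZM (log2 fold change -5.59, adjusted p = 0.033), and leaving out any array but microglia replicate 2 ended this call, with log2 fold changes of -4.42 to -5.70 (adjusted p = 0.054 to 0.11).

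The third comparison, microglia against DC, gives the background for both. Microglia carried Fcrls (log2 fold change 8.17), Il1a (7.74) and C3ar1 (7.44) above DC, while Ifi205 (-7.72), Clec9a (-7.47) and Dnase1l3 (-7.46) were lower. In all, 2224 genes were called, 1026 higher and 1198 lower in microglia. The macrophage core was higher for 35 of 36 members (adjusted p = 3.6e-35), and the microglia list for 22 of 23 (adjusted p = 1.3e-29). Of the DC list 27 of 28 were lower (adjusted p = 1.7e-30), of type 1 DC genes 16 of 17 (adjusted p = 1.7e-20), of class II genes 13 of 18 with 1 higher (adjusted p = 1.8e-11), of maturation genes 12 of 17 (adjusted p = 6.0e-12), of class I genes 7 of 18 (adjusted p = 7.2e-06) and of cell cycle genes 23 of 29 (adjusted p = 8.9e-20). Complement and Fc genes were higher for 11 of 18 and lower for 2 (adjusted p = 8.7e-09).

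With an estimated correlation 11 list calls held for TZM against DC: macrophage core, microglia, DC, type 1 DC, lymph node macrophage, lysosome, lipid, class II, maturation, complement and Fc, and cell cycle. For TZM against microglia 8 held: macrophage core, microglia, DC, class I, class II, maturation, interferon and immediate early. For microglia against DC 9 held: macrophage core, microglia, DC, type 1 DC, class I, class II, maturation, complement and Fc, and cell cycle. Several other lists were called for microglia against DC with the preset correlation alone. Lysosomal genes had 21 higher and 3 lower of 47 (adjusted p = 0.11 with an estimated correlation), efferocytosis genes 14 higher and 4 lower of 36 (adjusted p = 0.12), immediate early genes 11 higher and 1 lower of 23 (adjusted p = 0.057), cytokines 11 higher and 6 lower of 30 (adjusted p = 0.39), and lymph node macrophage genes 8 higher and 4 lower of 19 (adjusted p = 0.35). The cytokine call ended without microglia replicate 1 (adjusted p = 0.051), and that of lymph node macrophage genes with the level filter (adjusted p = 0.098). Not called with the preset correlation were lipid handling (7 higher, 3 lower of 22, adjusted p = 0.068, but 0.039 with median centring, 0.045 without TZM replicate 2 and 0.038 without DC replicate 1), interferon-stimulated genes (4 higher, 6 lower of 25, adjusted p = 0.13) and regulators (11 higher, 9 lower of 28, adjusted p = 0.65, with a median of -0.11 and a mean of 0.56).

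**Figure D3:**
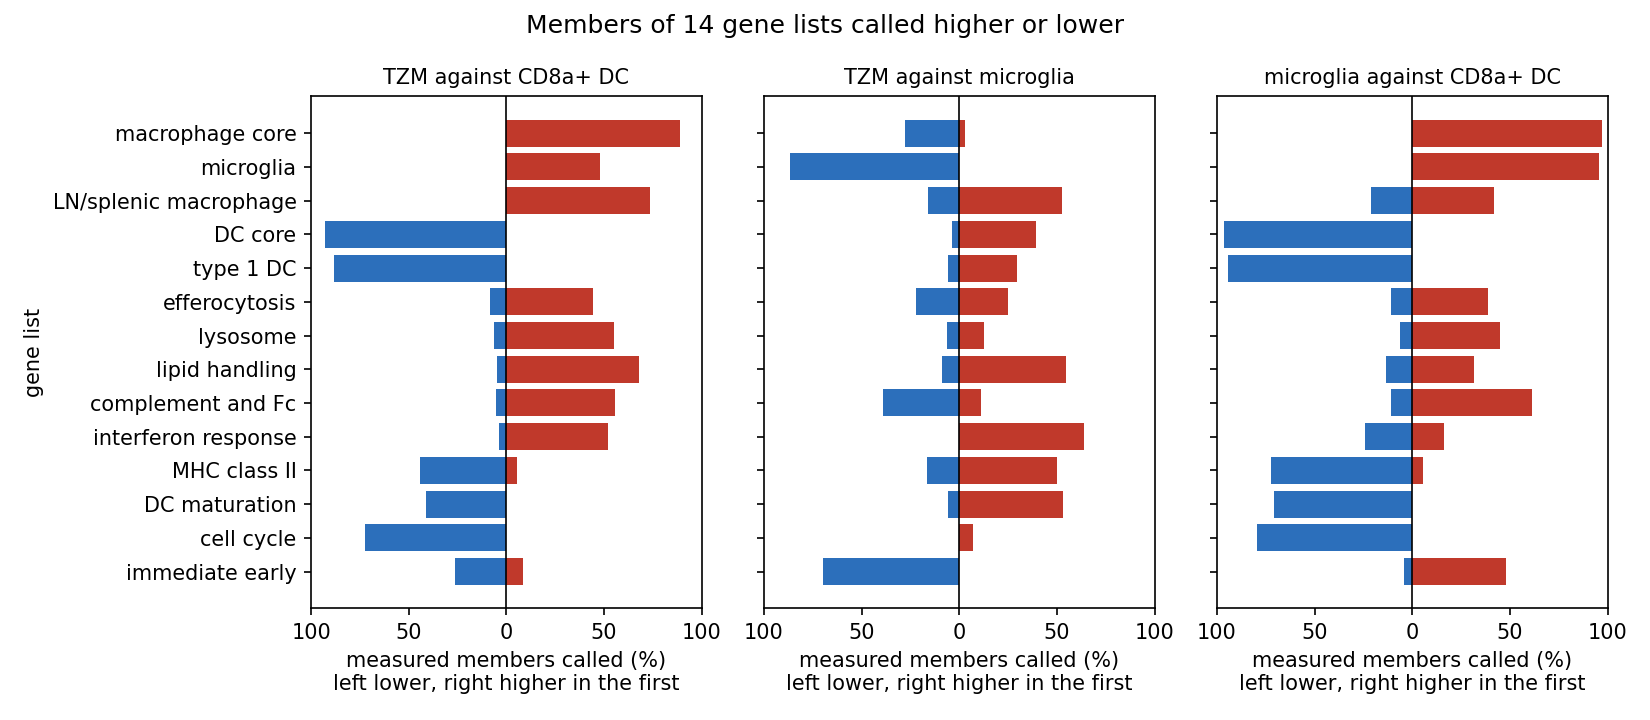
Share of the measured members of 14 gene lists (y axis) called higher (red, to the right) or lower (blue, to the left) in the first population of each comparison (x axis, percent). The DC core list points left in both comparisons with DC (26 and 27 of 28 members) and mostly right for TZM against microglia (11 of 28).

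TZM and microglia shared many differences from DC. Higher in both were 461 genes, against 48.3 for independent lists of these sizes, and lower in both were 591, against 48.3. Simulations of unchanged groups gave 0 shared genes, as the calling criteria leave almost no calls there, and so do not measure what shared arrays add. Opposite directions were rarer, with 45 genes higher in TZM and lower in microglia than in DC (56.4 for independent lists) and 11 the other way (41.4). Part of the excess may come from the shared DC arrays. The independent lists were also taken over all 19938 genes, of which 7678 passed the level filter. Genes under that level were seldom called, which adds to the excess.

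Genes higher in TZM than in both other populations numbered 410 (39.9 for independent lists), and those lower than in both 118 (27.3). Here the TZM arrays are shared, and part of the excess may come from them and from counting dim genes. Named among the former by the rule were Pla2g2d, Bpifa2, Smr3a, the complement factor Cfb, Ccl8, the chemokine receptor Cxcr2, Clec4n, the transglutaminase Tgm1, the growth factor Igf1 and Timd4. Several of these were near the low end of the scale in DC and microglia, so the order of their differences was not read. Cfb was at 11.64 ± 0.15 in TZM, 5.65 ± 0.05 in DC and 5.41 ± 0.36 in microglia, and Igf1 was at 10.53 ± 0.09, 4.88 ± 0.17 and 5.47 ± 0.45. Bpifa2 and Smr3a, which encode salivary proteins, varied most among these, with TZM levels of 10.51 ± 1.37 and 9.34 ± 1.02. Lower than in both were Rasgrp3, Xist, St3gal5, Arsb, Nr4a1, Alox5ap, Ckb, Tagap, Hhex and Chn2. Alox5ap, needed for leukotriene synthesis, was at 7.72 ± 0.20 in TZM, 11.05 ± 0.07 in DC and 10.78 ± 0.02 in microglia.

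Genes of the sort gates followed the gates in part. Itgam (CD11b) was at 7.84 ± 0.01 in TZM, 4.14 ± 0.19 in DC and 10.76 ± 0.05 in microglia, Itgax (CD11c) at 8.25 ± 0.09, 10.06 ± 0.03 and 5.37 ± 0.18, and Ptprc (CD45) at 10.38 ± 0.15, 10.76 ± 0.02 and 10.12 ± 0.19. Siglec1, which encodes CD169, was at 7.38 ± 0.69 in TZM, sorted as CD169 negative, and at 4.89 ± 0.22 in DC. Of 11 gate genes, 5 were higher and 3 lower in TZM than in DC, and likewise than in microglia. In microglia 4 were higher and 5 lower than in DC. The list was called in no comparison (camera adjusted p = 0.48, 0.37 and 0.83 for TZM against DC, TZM against microglia and microglia against DC). Camera looks for a shift of the list in a single direction, so it says little about genes that go both ways.

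Lists of markers of other cells were called in every comparison, most often as higher in TZM than in microglia. None of these calls held with an estimated correlation. For TZM against DC these were neutrophil (3 of 12 higher, adjusted p = 0.21 with an estimated correlation), T cell (2 of 12 higher, adjusted p = 0.28) and stromal markers (2 of 11 higher, adjusted p = 0.21). For TZM against microglia they were neutrophil (3 of 12 higher, adjusted p = 0.28), T cell (4 higher and 1 lower of 12, adjusted p = 0.23), B cell (3 higher and 1 lower of 14, or 4 higher adjusted over the list alone, adjusted p = 0.059), NK cell (3 of 10 higher, adjusted p = 0.17), monocyte (4 of 9 higher, adjusted p = 0.35) and type 2 DC markers (2 of 11 higher, adjusted p = 0.21). For microglia against DC only plasmacytoid DC markers were called (2 higher and 3 lower of 8, adjusted p = 0.060 with an estimated correlation). Plasma cell, red cell, neuron, astrocyte, oligodendrocyte and endothelial lists and the sex-linked list were called in none by the main camera test. Fry, which does not compare a list with other genes, called each of these but the oligodendrocyte list in at least 1 comparison. Under other single alternatives astrocyte markers gained a call in TZM against DC (level filter, adjusted p = 0.046, without TZM replicate 3, adjusted p = 0.041, and without microglia replicate 1, adjusted p = 0.045). Plasma cell (adjusted p = 0.027) and monocyte markers (adjusted p = 0.0094) gained calls in microglia against DC with the level filter. The sex-linked list gained calls without TZM replicate 3 (adjusted p = 0.041 against DC and 0.039 against microglia) and with median centring against DC (adjusted p = 0.041). NK cell markers did in TZM against DC without TZM replicate 1 (adjusted p = 0.014), and B cell markers in microglia against DC without TZM replicate 1 or 2 or DC replicate 1 and with the replicate block (adjusted p = 0.038 to 0.045). Calls in TZM against DC ended for T cell markers without DC replicate 1 or 3 or any microglia array (adjusted p = 0.051 to 0.083), and for stromal markers without DC replicate 1 (adjusted p = 0.083). In TZM against microglia the monocyte call ended without TZM or microglia replicate 2 (adjusted p = 0.056 and 0.051). The level filter also ended the T cell calls (adjusted p = 0.40 and 0.69), the B cell and type 2 DC calls (adjusted p = 0.38 and 0.077) and the plasmacytoid DC call (adjusted p = 0.15). Adjusted over the list alone, monocyte markers had 1 more member higher against DC and 1 more lower against microglia in TZM, and astrocyte markers 1 more higher against DC. Median and mean also differed in sign for the gate, type 2 DC, oligodendrocyte and endothelial lists in TZM against DC, for the endothelial list in TZM against microglia, and for the gate, sex-linked, plasma cell, neutrophil, monocyte, type 2 DC and endothelial lists in microglia against DC. In the sex-linked list, 3 of 4 genes were higher and 1 lower in TZM in both comparisons: Xist was at 4.16, 4.36 and 8.26 in the 3 TZM arrays, against 10.03 ± 0.12 in DC and 10.45 ± 0.10 in microglia, and Eif2s3y at 6.67, 7.37 and 5.48 against 2.99 ± 0.09 and 2.93 ± 0.11. The sex of the mice is not stated in the labels used here. TZM replicate 2 differed at least 2-fold from the mean of the other 2 TZM arrays in 311 genes. The same count was 10 to 111 in the other 8 arrays.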

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

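3 alternatives were chosen only after the data were seen: TZM replicate 3 as the only TZM array, no X or Y chromosome genes, and no genes that differ by at least 1 between TZM arrays. Without a minimum fold change the counts became 4025 (TZM against DC), 3873 (TZM against microglia), 5006 (microglia against DC), 872 and 471 (higher and lower in TZM than in both), and 1034 and 1459 (higher and lower in both macrophage populations than in DC), by dropping a criterion. With every probe set tested, 2333 were called for TZM against microglia, 3440 for microglia against DC and 215 as lower in TZM than in both, over more features. With 1 minus Pearson correlation the difference of distances was 0.0074, on another scale and in the same direction. List calls for TZM against DC, TZM against microglia and microglia against DC were 17, 20 and 15 with camera, 11, 8 and 9 with an estimated correlation (24 calls lost, 0 gained), and 26 and 27 for the comparisons with DC under fry (29 gained over all 3), which does not compare a list with other genes.

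With 1 array left out, calls ran from 1655 to 1814 for TZM against DC, 1472 to 1558 for TZM against microglia and 2132 to 2234 for microglia against DC. The conjunctions ran from 401 to 447, 109 to 125, 446 to 477 and 533 to 615, the difference of distances from 4.99 to 6.96, and list calls from 15 to 19, 19 to 20 and 14 to 17. TZM replicate 3 as the only TZM array gave 1784 and 1547 calls, of which 1533 and 1317 were among the 1743 and 1526, assuming that it varies like the other groups. The other count alternatives stayed within 1.5 times. Whether equal numbers pair the samples could not be told with so few arrays. Same-number arrays correlated at -0.15 to 0.13 (1 of 9 pairs over 0.1), and arrays of different number at -0.19 to 0.15. Of 9 arrays, 5 lay closest to their own number. With the replicate block the counts were 1732, 1510 and 2213 and the difference of distances 6.15. Of 345 called values of named genes, 318 stayed called under all 21 alternatives that kept the gene, and 0 changed sign. The calls of Ttr and Ms4a4c for TZM against microglia, Cd74 for TZM against DC and F13a1 for microglia against DC ended most often. The probe sets of Top2a and Wdfy4 disagreed in sign for TZM against microglia, and those of Top2a also for microglia against DC (-3.80 and 0.22). Signal over background was not analysed here, which limits statements on dim genes.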

Other observations

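Tests of the sex-linked levels themselves, of the range of the salivary genes, of Cd28 and Cxcr2, and of which splits kept a population whole were chosen only after the result was seen. Some genes known from other lineages stood high in TZM. Ehf, an epithelial transcription factor chosen here after its values were seen, was at 9.04, 8.83 and 8.66 in TZM, and higher than in DC by 2.70 and than in microglia by 4.61. The endothelial cadherin Cdh5 was at 7.65 ± 0.11 in TZM, 5.38 ± 0.15 in DC and 5.24 ± 0.08 in microglia, while 10 of the 12 endothelial genes were not called against DC. Ccl19, a T zone chemokine, was at 8.68 ± 0.19 in TZM, 6.97 ± 0.19 in DC and 5.78 ± 0.18 in microglia.

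Salivary gland transcripts were high in the TZM arrays: Bpifa2 was at 10.24, 11.998 and 9.29, and Smr3a and 4 genes chosen after their values were seen (Amy1 and the uncalled Car6, Pip and Cst10) were likewise highest in TZM replicate 2. A candidate source is salivary gland tissue taken along with nodes, although the sort should remove its cells. A prediction for 16 other secretory genes, listed before their values were seen, failed: the median difference was 0.026 from DC and 0.090 from microglia, 0 of 16 were called higher than in both, and of 13 epithelial genes 1 was (Ehf). As a set, the 16 genes thus gave no sign of RNA of salivary glands in general. However, several of them, such as Smgc, Prol1 and Smr2, lay near the low end of the scale in every population. A small share of gland RNA could go unseen there. The list also mixes several glands. Of its members Dcpp1 (0.63 and 0.66, adjusted p = 0.042 and 0.036) and Dcpp3 (0.58 and 0.57, adjusted p = 0.00052 and 0.00068) were higher than in DC and in microglia under the fold minimum, so a single gland stays open. The 6 genes ranged over 2.97 between TZM arrays (median), against a 95th percentile of 1.60 for the 410 genes higher in TZM than in both. However, 4 of them were picked for that spread. Bpifa2 and Smr3a, named by the rule, ranged over 2.71 and 2.02, also above 1.60. So few genes cannot decide, and steady expression by TZM stays open too.

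Sex-linked genes set the TZM arrays apart. In 4 of 4 genes (Xist, Eif2s3y, Kdm5d and Uty) TZM replicate 3 lay between replicates 1 and 2 and the other 6 arrays, which is consistent with male RNA in TZM replicates 1 and 2, a mix in replicate 3 and female RNA in the rest, so that sex is confounded with population. If sex set the 510 autosomal genes apart from both groups, replicate 3 should lie part of the way, as for the Y-linked genes (ratio to replicates 1 and 2 of 0.45 to 0.62). The median ratio was 1.005, with a 5th percentile of 0.70 and 97.3% of genes above 0.62, which passed the bound set beforehand against sex as the cause. That bound asked too little for this design, since it reads a single array and no other array mixes the sexes. The 510 genes were also called with replicate 3 among the TZM arrays, which tends to pass over genes with a low ratio. Sex and population therefore cannot be told apart for these genes.

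Cd28 and Cxcr2, known from T cells and neutrophils, were higher in TZM by 4.84 and 5.74 than in DC, although the gates on MertK and GFP should remove both cell types. T cell RNA is unlikely to account for Cd28, since the other 11 markers had medians of at most 0.14, with Cd3e at 6.14 ± 0.21 in TZM and 5.61 in DC and with Thy1 the only other one higher than in both (by 1.27 than in DC, and by 1.11 with adjusted p = 0.052 without DC replicate 3). Cd3d and Cd3g were higher than in microglia, so that a small share of T cell RNA stays open. Neutrophil RNA is unlikely to account for Cxcr2, since the other 11 markers had medians of at most 0.20, and S100a8 ran from 5.89 to 9.28 across TZM arrays while Cxcr2 ran from 8.77 to 9.29. S100a8 and S100a9 were higher than in DC by 3.27 and 2.88 (the latter not called when only the compared groups were fitted, adjusted p = 0.052), and a neutrophil source of both, like expression of Cd28 and Cxcr2 by TZM, stays open.

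Splits of the 6 arrays of a comparison are too few, at 10, for a share under 0.05: 1 of 10 gave as many genes in each, with 1743, 1526 and 2224 genes in the real split and at most 0 in the others. For the conjunctions 100 splits of the 9 arrays into 3 groups were drawn. As many genes were found in 1 split for those higher in TZM than in both (410, highest other 388), in 2 for those lower (118, highest other 290), and in 1 each for those higher (461, highest other 390) and lower (591, highest other 553) in both macrophage populations. These shares lay under 0.05 but cannot exclude chance, since a split that mixes the populations leaves little to call. The 90 splits that kept no population whole gave 0 genes each. Counts over 0 in other splits all came from the 9 that kept 1 population whole.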
